A study of Arabidopsis thaliana with 12 samples.

How the data were processed

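The study hybridised biotin-labelled cRNA, made from about 10 µg of total RNA of whole 7-day seedlings, to Affymetrix ATH1 arrays, per the labels. About 100 mg of tissue went into each TRIzol extraction with RNeasy purification. Per the submitters' processing notes the software GCOS 1.1.1 was used; its settings are not given in the sources used here. The deposited values are probe set intensity on a linear scale. Their 2% trimmed mean was close to 500 on all 12 arrays, as computed from the values, and the scaling step behind this is not given in the sources used here. Because these trimmed means differed by far less than 10%, the values were used as deposited. The table held 22810 probe sets, 64 of them controls. No column belonged to another sample.

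Samples were grouped by their titles into Ws mock, rop10-1 mock, Ws ABA and rop10-1 ABA, with 3 arrays each. The design text describes the replicates as biological. Probe sets were named through the platform's probe table, which can be old. It gave 13513 probe sets a single gene, 503 several genes and listed none for 8730, which are unnamed here and not without a gene. Of the 15923 tested probe sets, 8722 had a single gene, 316 several and 6885 none listed. Of those with a single gene, 8699 matched a locus of a RefSeq gene table (assembly TAIR10.1), 8604 loci in all, which was used only for names and neighbour order. Probe sets with several genes or none were not named. No probe set was assigned to ROP10, so the check of the mutated gene was not made.

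Values were tested as log2(value + 16) with limma 3.58.1 in R 4.3.3. Fold changes are on that scale, which understates the change of low genes. Control probe sets and the 30% with the lowest mean over all arrays were left out. A single fit held 1 mean per group for all 12 arrays, with eBayes and an intensity trend, two-sided tests and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was a call. The comparisons were ABA against mock in each genotype, rop10-1 against Ws in each treatment, both averages and the interaction. The size of the ABA response was the mean log2 value per array over the probe sets called in the average ABA response. Its difference between genotypes was tested by exact permutation of genotype labels within treatment (400 arrangements, two-sided).

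Fixed gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, with camera at an estimated correlation and fry as alternatives. Of 26 lists only the ABA-induced markers and the expansins and xyloglucan enzymes reached 5. Smaller lists were counted gene by gene: transcription factors of ABA, ABA synthesis and turnover, auxin, cytokinin and jasmonate genes, defence, light harvesting, root hairs, guard cells, heat shock, handling, clock, hypoxia, sugar starvation, anthocyanin and reference genes. Measured here means that a tested probe set was assigned to that gene alone. For the lists of clade A PP2C phosphatases, PYR/PYL receptors, SnRK2 kinases, gibberellin genes, seed storage and cell division the probe table named no single-gene probe set. These lists gave no result, but their genes may be among the unnamed probe sets and are not thereby absent from the arrays. The other fixed lists are not reported here.

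Named genes were, per comparison, the 10 that rose most and the 10 that fell most among calls whose groups of 3 arrays did not overlap (for averages and the interaction, among all calls), if the probe set had a single gene. Where fewer than 5 passed, the 5 with the smallest p were taken, and up to 4 members of each list were added. The comparisons, the tests, the naming rule, the lists and all alternative settings but the last were chosen before the data were examined. Alternatives were the pseudocount (1 or 64), the low filter, quantile normalization, median centring, no intensity trend, array weights, the replicate block, a 2-fold minimum, shared-probe IDs left out, a fit of the groups compared alone and each array left out. Leaving out all arrays of a number, the last setting, was chosen after seeing the data.

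The replicate numbers in the titles paired the samples. Deviations from group means correlated between arrays of the same number in different groups at r = 0.215 to 0.711 over 18 pairs, and between different numbers at -0.475 to 0.11. Each of the 12 arrays was closest to its own number. The source of this pairing is not given in the sources used here. Values with the replicate number as a block are printed where they move a count by over 1.5 times or change the call of a gene in the comparison that named it.

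The procedure was tested on simulated data with 200 changed genes among 15923, in 5 runs. For the ABA response in Ws it recovered 61.6% of 2-fold and 94.8% of 4-fold changes, with a false share of 0.628%. With the block these were 82.2%, 98.6% and 4.63%. The simulated arrays were drawn from the fit with the block, with additive number effects and independent noise per gene. This setting favours the block and leaves out correlation between genes.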

Results

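RNA from whole Arabidopsis thaliana seedlings was measured on 12 Affymetrix ATH1 arrays, which read each gene with a set of short probes. The seedlings were either wild type of the Ws accession or carried rop10-1, a mutation in ROP10, a small GTPase. After 7 days in shaken liquid medium they received 1 µM abscisic acid (ABA), the hormone of drought and seed dormancy, or the solvent DMSO as a mock treatment, for 4 hours. The 4 groups, Ws mock, rop10-1 mock, Ws ABA and rop10-1 ABA, held 3 biological replicates each, so the number of arrays limits the precision. The deposited signal had a 2% trimmed mean of 500.04 to 500.048 on every array and a median of 180.05 to 203.15. No probe set could be assigned to ROP10 from the probe table used here, so the mutated gene itself was not analysed here. RNA quality was compared through 3'/5' signal ratios of control transcripts. The ubiquitin log2 ratio was 0.41 ± 0.062 (SD, n = 6) with ABA and 0.51 ± 0.047 in mock, the lowest p of 8 exact permutation tests (two-sided p = 0.0152, 0.122 after Benjamini-Hochberg adjustment).

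The first comparison asked what ABA does in the wild type. AT3G02480 and LEA4-5, genes of late embryogenesis abundant (LEA) proteins, which accumulate in drying tissue, had the largest increases in Ws. AT3G02480 went from a signal of 17.37 ± 13.4 to 2561 ± 923 (SD, n = 3 each), a log2 fold change of 6.30 (SE 0.39, adjusted p = 2.8e-06). LEA4-5 went from 17.1 ± 14.3 to 1510 ± 215 (5.60, SE 0.26, adjusted p = 2.5e-07). The LEA family gene AT3G17520 rose by 4.47 (SE 0.32), and COR15A, which encodes a chloroplast LEA protein of cold acclimation, rose by 3.86 (SE 0.29) from a signal of 199 ± 39.2 to 3120 ± 623. On the falling side AT4G21870, a gene of the small heat shock protein type, went from 3724 ± 1710 to 422 ± 217 (-3.10, SE 0.42, adjusted p = 0.00067).

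Other genes with large increases in Ws were the jacalin-type lectin gene AT5G28520 (5.0, SE 0.46), the TRAF-like gene AT3G28220 (4.29, SE 0.39) and AT1G16850 (4.03, SE 0.52). The lipid-transfer-like genes AT2G37870 and AT4G33550 rose by 3.90 (SE 0.19) and 3.88 (SE 0.17), and the WD40 repeat gene AT1G49450 by 3.86 (SE 0.23). Among the decreases, the peroxidase gene AT5G19890 changed by -2.54 (SE 0.60), the extensin-like gene AT1G26250 by -2.40 (SE 0.29), TBL45 of the trichome birefringence-like family by -2.01 (SE 0.20) and the peroxidase gene Prx37 by -2.0 (SE 0.29). UGT72E1, a glucosyltransferase of monolignols, changed by -2.23 (SE 0.32) and the ERF transcription factor gene AT5G61590 by -2.16 (SE 0.20). AT1G66940, AT4G39675 and AT5G28630 changed by -2.15, -2.10 and -1.97. The adjusted p of these 15 genes and of the 5 above was at most 0.025, and the ABA and mock arrays did not overlap for any of them.

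Of the 31 genes in the fixed list of ABA-induced markers, 5 had a tested probe set assigned to them. All 5 rose in Ws, also when adjusted over the list alone. Besides LEA4-5 and COR15A these were COR15B (2.38, SE 0.24), the dehydrin LTI30 (2.16, SE 0.23) and the dehydrin COR47 (0.98, SE 0.25, adjusted p = 0.0385). The list shifted upwards by a mean of 3.00 (camera adjusted p = 1.95e-12, and adjusted p = 0.000831 with an estimated correlation). Of the 11 genes in the anthocyanin list, only the enzyme genes DFR and UF3GT had a tested probe set assigned to them. They rose by 2.44 (SE 0.27) and 2.17 (SE 0.20), both also when adjusted over the list alone. WES1, an auxin-conjugating enzyme gene and 1 of 3 measured auxin-induced genes, rose by 1.5 (SE 0.19), while GH3.3 had 0.62 (SE 0.58) and LBD16 -0.14 (SE 0.26). No member of the 5 expansins and xyloglucan enzymes passed over all genes, and the list did not shift (camera adjusted p = 0.896). Adjusted over the list alone, 1 member was higher and 1 lower. EXPA4 had 1.01 (SE 0.29, adjusted p = 0.057, 0.00143 with the replicate number as a block) and EXPA8 -1.33 (SE 0.43, adjusted p = 0.0917, 0.0162 with the block). XTH18, XTH19 and XTH20 had -0.45, 0.34 and -0.25.

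The organ and cell type markers gave no call over all genes in Ws. The root hair genes EXPA7 and EXPA18 had -0.22 (SE 0.18) and -0.03 (SE 0.21), and the light-harvesting genes LHCB4.1 and LHCB4.2 had -0.01 (SE 0.099) and -0.09 (SE 0.24). The guard cell gene AT1G22690 had -0.84 (SE 0.30, adjusted p = 0.135, 0.0419 with the block) and was the 1 guard cell marker that was lower when adjusted over the list alone, with FMA at -0.04 (SE 0.15). Lists with a single measured member gave no call over all genes or, without the block, over the list alone. Adjustment over a list of 1 gene leaves its p unchanged, so such a gene passes over the list alone at an unadjusted limma p under 0.05. With the block ATHSP22.0 was higher and PDF1.2 and STZ lower at that limit. The single members included the bZIP gene EEL (-0.18, SE 0.32), the ABA glucosyltransferase UGT71B6 (0.26, SE 0.32), RR16 (0.10, SE 0.66), PDF1.2 (-0.56, SE 0.88), WRKY53 (0.15, SE 0.36), ATHSP22.0 (0.49, SE 0.23), STZ (-0.61, SE 0.78), GI (-0.34, SE 0.23), AT3G10040 (-0.34, SE 1.37) and MCCA (-0.22, SE 0.22). The reference genes PEX4 and AT4G34270 had -0.01 (SE 0.16) and -0.05 (SE 0.16).

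In all, 1042 of 15923 tested probe sets changed with ABA in Ws by limma at an adjusted p under 0.05, 645 up and 397 down, and 498 of them at least 2-fold. The 3 ABA and 3 mock arrays did not overlap for 21.2% of all tested probe sets, against 10% by chance. With the replicate number as a block the count was 2495, 1259 up and 1236 down, with all 1042 among them, and it fell to 1483 without Ws mock 2 and 1596 without Ws ABA 3. Without the block it was 686 without Ws mock 2, and 571 in a fit of the 6 Ws arrays alone.

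The second comparison asked what ABA does in rop10-1. AT3G02480 and LEA4-5 again had the largest increases. AT3G02480 rose by 6.41 (SE 0.39, adjusted p = 2.1e-06), from 18.1 ± 12.7 to 2799 ± 841 (SD, n = 3 each), and LEA4-5 by 5.79 (SE 0.26), from 9.6 ± 6.44 to 1377 ± 131. AT5G28520 rose by 5.05 (SE 0.46), AT1G49450 by 4.31 (SE 0.23), AT3G17520 by 4.08 (SE 0.32) and AT2G37870 by 3.72 (SE 0.19). AT3G22620 rose by 3.70 (SE 0.27), AT5G53710 by 3.68 (SE 0.41), AT4G33550 by 3.66 (SE 0.17) and AT1G16850 by 3.60 (SE 0.52).

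AT4G21870 had the largest decrease in rop10-1 (-3.70, SE 0.42), from 4298 ± 386 to 328 ± 113. AT1G26250 followed at -2.98 (SE 0.29), then AT5G62360, of the pectin methylesterase inhibitor family, at -2.90 (SE 0.23). AT5G19890 had -2.74 (SE 0.60), AT4G39675 -2.54 (SE 0.19), AT1G66940 -2.39 (SE 0.22) and Prx37 -2.37 (SE 0.29). The pectin lyase-like gene AT5G63180 had -2.33 (SE 0.25), AT5G61590 -2.22 (SE 0.20) and BZIP61, a bZIP transcription factor gene, -2.12 (SE 0.40). The adjusted p of these 20 genes was at most 0.0167, and the plot of log2 fold changes in both genotypes shows most of them.

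**Figure D1:**
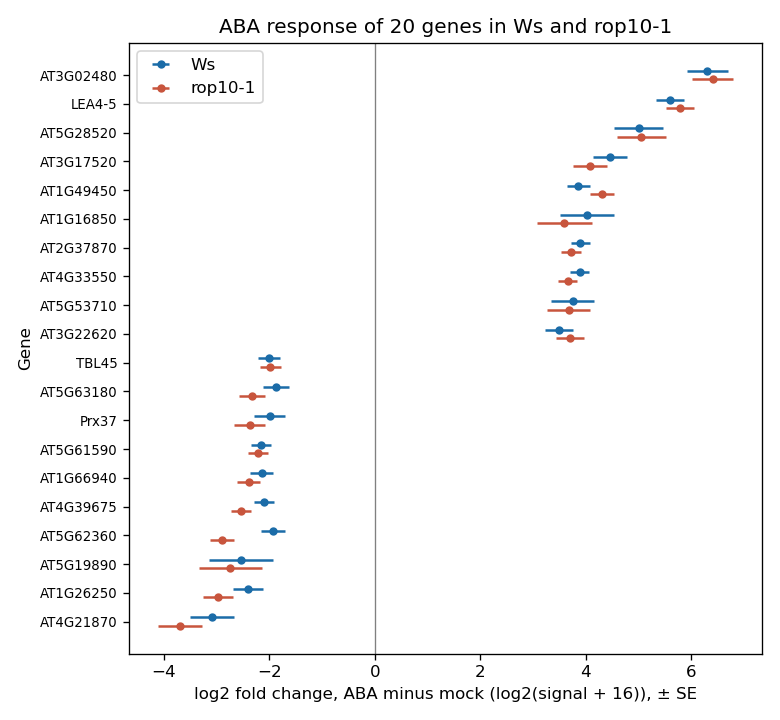
Log2 fold change (ABA minus mock, on the log2(signal + 16) scale) of the 10 genes with the largest increase and the 10 with the largest decrease in the average ABA response, in Ws (blue) and rop10-1 (red), with points for the estimate and bars for ± 1 SE (n = 3 arrays per group). AT3G02480 sat at 6.30 in Ws and 6.41 in rop10-1, and AT4G21870 at -3.10 and -3.70.

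All 5 measured ABA-induced markers rose in rop10-1 too, also when adjusted over the list alone, with a mean of 2.69 (camera adjusted p = 2.14e-11, and adjusted p = 0.00114 with an estimated correlation). COR15A rose by 3.28 (SE 0.29), LTI30 by 1.93 (SE 0.23), COR47 by 1.28 (SE 0.25) and COR15B by 1.17 (SE 0.24, adjusted p = 0.0127). DFR rose by 0.98 (SE 0.27, adjusted p = 0.0491), UF3GT by 0.95 (SE 0.20, adjusted p = 0.0129) and WES1 by 1.68 (SE 0.19), all 3 also when adjusted over the list alone. Among the expansins EXPA4 rose by 1.29 (SE 0.29) and EXPA8 changed by -2.12 (SE 0.43, adjusted p = 0.0102). XTH20 had -0.66 (SE 0.20, adjusted p = 0.074, 0.00427 with the replicate block) and was the further member lower when adjusted over the list alone. The list as a whole did not shift (camera adjusted p = 0.613). The guard cell gene AT1G22690 changed by -1.49 (SE 0.30, adjusted p = 0.0104), while FMA had -0.04 (SE 0.15). UGT71B6 had 0.69 (SE 0.32, adjusted p = 0.273, 0.0122 with the block). No other fixed list had a call in rop10-1 over all genes, and only with the block was GH3.3 higher when adjusted over the list alone. UGT71B6 and WRKY53, each the single measured member of its list, were higher at an unadjusted limma p under 0.05 only with the block. EXPA7, EXPA18, LHCB4.1 and LHCB4.2 had 0.19, 0.23, 0.05 and -0.23, and the reference genes PEX4 and AT4G34270 0.07 and -0.17.

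In rop10-1, 1041 probe sets changed with ABA by limma, 641 up and 400 down, 488 of them at least 2-fold. The arrays of the 2 groups did not overlap for 27.9% of all tested probe sets, against 10% by chance. The count was 2486 with the replicate block (1291 up, 1195 down, all 1041 among them), where it fell to 1409 without rop10-1 mock 1, 1607 without rop10-1 mock 3 and 1572 without rop10-1 ABA 3, and 2481 with array weights. Without the block it was 693 without the rop10-1 mock array numbered 2, 627 without rop10-1 mock 3 and 611 without rop10-1 ABA 3.

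Of the probe sets called in the separate tests, 471 rose in both genotypes, where independent lists would share 26.0, and 243 fell in both, where they would share 9.97. With the replicate block 928 rose and 693 fell in both, against 102 and 92.8. None moved in opposite directions in either case. Of the 328 called in Ws alone, 319 had the same sign in rop10-1, and of the 327 called in rop10-1 alone, 319 had the same sign in Ws. Across genes, which are not independent replicates, the ABA fold changes in Ws and rop10-1 had Pearson's r = 0.844 and a Spearman correlation of 0.655. Averaged over both genotypes (6 against 6 arrays), AT3G02480 rose by 6.36 (SE 0.28), LEA4-5 by 5.70 (SE 0.19) and AT5G28520 by 5.03 (SE 0.33). AT4G21870 had -3.40 (SE 0.30) and AT1G26250 -2.69 (SE 0.20). In this average 2475 probe sets changed, 1307 up and 1168 down, 566 of them at least 2-fold, and 4455 with the replicate block (1985 up and 2470 down). The markers shifted by a mean of 2.84 (camera adjusted p = 4.97e-11, and adjusted p = 0.00128 with an estimated correlation), all 5 having risen, and of the expansins and xyloglucan enzymes 1 rose and 2 fell (camera adjusted p = 0.848). ATHSP22.0, the single measured member of its list, was higher at an unadjusted limma p under 0.05 and failed over all genes. UGT71B6 had 0.48 and GH3.3 0.74, both of which passed over all genes and over the list alone only with the replicate block (adjusted p = 0.00777 and 0.0369 over all genes). PDF1.2 and MCCA, each the single measured member of its list, were lower at an unadjusted limma p under 0.05 only with the block.

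The third comparison asked what the mutation changes without added ABA. Fes1C, which encodes an Hsp70 co-chaperone of the Fes1 type, was higher in rop10-1 mock than in Ws mock, at 684 ± 68.3 against 259 ± 33.0 (SD, n = 3 each), a log2 difference of 1.35 (SE 0.16, adjusted p = 0.0189). AT5G01350 was higher at 1132 ± 162 against 433 ± 29.6 (1.35, adjusted p = 0.0189). AT5G01015 was lower at 114 ± 4.05 against 340 ± 83.3 (-1.42, adjusted p = 0.0319). Of the called probe sets that have no gene in the table used here, 1 was higher in rop10-1 by 3.31 and 1 lower (-1.57). The 3 genes are plotted per array.

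**Figure D2:**
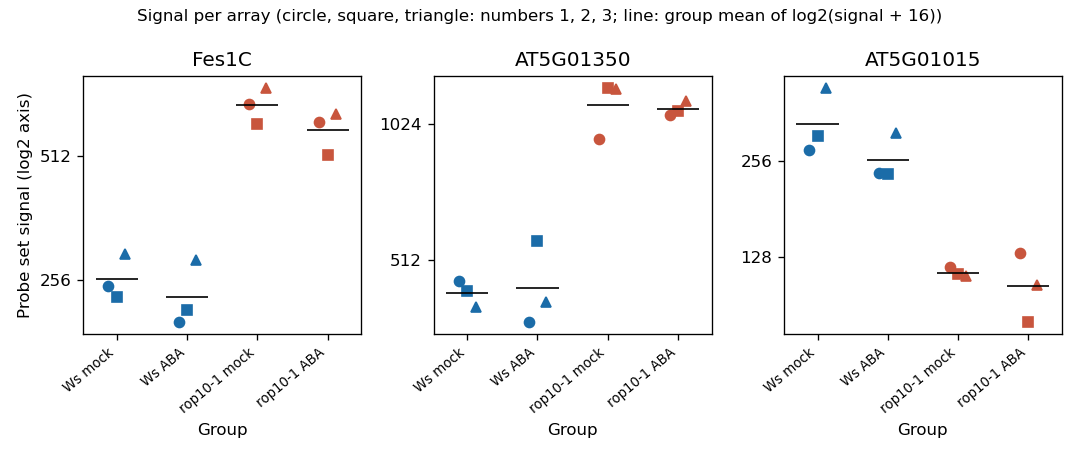
Signal of Fes1C, AT5G01350 and AT5G01015 on each of the 12 arrays (log2 axis), by group, with circles, squares and triangles for replicates numbered 1, 2 and 3 and lines for group means taken on the log2(signal + 16) scale. In mock, Fes1C averaged 259 in Ws and 684 in rop10-1, and AT5G01015 340 and 114.

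These 5 probe sets, 3 higher and 2 lower, were the only calls of limma in mock, and 594 had an unadjusted p under 0.05. The 3 rop10-1 and 3 Ws arrays overlapped for none of the 5, and for 9.4% of all tested probe sets they did not overlap, against 10% by chance. The replicate block gave 7 calls, from 2 to 10 with an array left out. Without the block the count was 0 when Ws mock 1, 2 or 3, rop10-1 mock 2 or 3 or rop10-1 ABA 3 was left out, 1 without rop10-1 mock 1, 2 without Ws ABA 2, 0 in a fit of the 6 mock arrays alone, 3 with no low filter and 2 with the lowest 50% left out. No fixed list had a call in mock over all genes or over the list alone. The ABA-induced markers had a mean of -0.04 but a median of 0.04 (camera adjusted p = 0.798), with LTI30 at 0.36 (SE 0.23) and COR47 at -0.33 (SE 0.25). The expansins and xyloglucan enzymes had a mean of 0.23 (camera adjusted p = 0.247), with XTH19 at 0.42 (SE 0.20). DFR and UF3GT had 0.35 (SE 0.27) and 0.39 (SE 0.20).

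The fourth comparison asked what the mutation changes under ABA. Fes1C was higher in rop10-1 ABA than in Ws ABA, at 594 ± 69.1 against 236 ± 45.1 (1.29, SE 0.16, adjusted p = 0.0201), and AT5G01350 at 1105 ± 40.1 against 450 ± 101 (1.29, adjusted p = 0.0201). The unnamed probe set that was higher in mock was also higher under ABA, by 3.93. AT5G01015 had -1.20 (adjusted p = 0.103, 0.0244 with the replicate block). The phosphatase gene SAL2 had 2.02 and AT2G04070, of the MATE transporter family, 1.66. Both failed with an adjusted p of 0.103 and passed with the block, at 0.0391 and 0.0379, as they did in the average over treatments (0.0259 and 0.0346 with the block). AT5G56980 (0.94) likewise went from 0.103 to 0.0391 under ABA.

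By limma 3 probe sets were called under ABA, all higher in rop10-1, and 1140 had an unadjusted p under 0.05. The arrays of the 2 genotypes did not overlap for these 3 and for 10.9% of all tested probe sets, against 10% by chance. Without rop10-1 ABA 1, without rop10-1 ABA 3 or in a fit of the 6 ABA arrays alone the count was 0, and with array weights 19. With the replicate block it was 43, 26 higher and 17 lower. Among the 20 of these that name a gene, chosen after their values were seen, AT1G26420 (2.77), AT2G04050 (2.75), AT3G28580 (2.49) and AT1G51850 (1.5) were higher in rop10-1. AT3G28220 (-2.26), JAL23 (-1.44), AT1G52000 (-1.35), COR15B (-1.16), DFR (-1.10), XTH32 (-0.83) and AT3G48460 (-0.83) were lower. That blocked count rested on single arrays, with 2 calls without rop10-1 ABA 3 and 375 without rop10-1 ABA 2. The ABA-induced markers had a mean of -0.35 and the list missed the threshold (camera p = 0.0366, adjusted p = 0.0733, and adjusted p = 0.259 with an estimated correlation). Without Ws ABA 1 its adjusted p was 0.0146, and without rop10-1 ABA 2 it was 0.0172. None of its 5 members passed over all genes, and adjusted over the list alone COR15B was lower (-1.16, SE 0.24, adjusted p over all genes 0.264, 0.0391 with the block). The expansins and xyloglucan enzymes had a mean of 0.10 but a median of -0.04 (camera adjusted p = 0.912). Adjusted over the list alone, both DFR (-1.10, SE 0.27) and UF3GT (-0.83, SE 0.20) were lower in rop10-1. The clock gene GI, the single measured member of its list, was higher (0.58, SE 0.23) at an unadjusted limma p under 0.05, as met by 7.16% of all tested probe sets. None of these 3 passed over all genes (adjusted p = 0.393, 0.369 and 0.613). With the block DFR passed (adjusted p = 0.0216). Only with it, adjusted over the list alone, was COR15A lower and XTH18 higher. UGT71B6, WRKY53 and STZ, each the single measured member of its list, were higher at an unadjusted limma p under 0.05 only with the block.

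Averaged over both treatments, 6 probe sets differed between the genotypes. Fes1C was higher by 1.32 (SE 0.11, adjusted p = 0.00038), as was AT5G01350 by 1.32 (SE 0.11, adjusted p = 0.00038), while AT5G01015 was lower (-1.31, SE 0.14, adjusted p = 0.0021). The other 3, which have no gene name here, had 3.62, -1.43 and -1.27. At an unadjusted p under 0.05 there were 1524. The count was 10 without Ws ABA 1 and also without Ws ABA 2, 15 with array weights, 3 with the lowest 50% left out and 227 with the replicate block, 144 higher and 83 lower. The blocked count moved from 7 without rop10-1 mock 2 to 626 without rop10-1 ABA 2. Across genes, the genotype differences in mock and under ABA had Pearson's r = 0.484 and a Spearman correlation of 0.358. Adjusted over the list alone COR15B was lower in rop10-1, and only with the block was DFR lower and XTH18 higher. PDF1.2 (lower), STZ and GI (both higher), each the single measured member of its list, had an unadjusted limma p under 0.05 only with the block. The ABA-induced markers had a mean of -0.19 (camera adjusted p = 0.19, and 0.0403 without Ws ABA 1) and the expansins and xyloglucan enzymes 0.16 (camera adjusted p = 0.337).

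The last comparison, which the series title names, asked whether the ABA response differs between the genotypes. The set of 1307 probe sets that rose in the average response did so by a mean of 0.951 in Ws and 0.945 in rop10-1, a difference of -0.00625 (SE 0.12, 95% interval -0.282 to 0.27, two-sided exact permutation p = 0.96). The 1168 that fell had means of -0.689 and -0.684, a difference of 0.00532 (SE 0.0316, 95% interval -0.0675 to 0.0782, two-sided exact permutation p = 0.9). These intervals and permutations did not use the pairing by replicate number. With the number as a block the 95% interval was -0.174 to 0.161 for the risen and -0.061 to 0.0717 for the fallen set. Genes with the largest increases had log2 fold changes in Ws and rop10-1 such as those of LEA4-5 (5.60 and 5.79), AT3G02480 (6.30 and 6.41) and AT5G28520 (5.0 and 5.05). AT3G28220, also among the largest increases in Ws, rose by 4.29 there and by 2.15 in rop10-1, an interaction of -2.14 (SE 0.55, adjusted p = 1). Without Ws ABA 1 the difference of the fallen set was 0.0672 (exact permutation p = 0.015, unadjusted), that is, a smaller decrease in rop10-1. There the set was chosen anew from groups of unequal size. Such a choice can favour this direction, so this p decides nothing.

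No probe set passed the interaction test of limma. The smallest adjusted p was 1, with 301 probe sets at an unadjusted p under 0.05, and with the replicate block it was 0.454, with 803. The 5 named genes with the smallest p all failed: AT5G52890 (0.94, SE 0.21), the actin regulator BRK1 (-0.70, SE 0.16), UF3GT (-1.22, SE 0.28), AT5G56980 (0.98, SE 0.23) and AT3G07180 (0.87, SE 0.21). The 95% interval of the interaction had a median half-width of 0.55 and excluded a 2-fold difference for 79.8% of probe sets. With the replicate block these were 0.445 and 89.9%. For the 2475 probe sets called in the average ABA response the values were 0.566 and 75.8% without the block. These intervals are not adjusted for the number of tests. Smaller differences were therefore not resolved for most genes, and larger ones could also fail over all genes. Adjusted over the list alone, DFR (-1.45, SE 0.38) and UF3GT of the anthocyanin list and COR15B (-1.21, SE 0.34) of the ABA-induced markers rose less in rop10-1, while over all genes each had an adjusted p of 1. DFR signal rose from 110 ± 31.6 to 680 ± 221 in Ws and from 143 ± 23.3 to 302 ± 73.4 in rop10-1 (SD, n = 3 each). The marker list as a whole had a mean interaction of -0.31 (camera adjusted p = 0.131), under 0.05 without Ws mock 1 (0.0453), rop10-1 mock 3 (0.0185), Ws ABA 1 (0.0391) or rop10-1 ABA 2 (0.021). COR47 and LEA4-5 gave positive interactions of 0.30 (SE 0.36) and 0.19, and the expansins and xyloglucan enzymes a mean of -0.13 (camera adjusted p = 0.257).

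**Figure D3:**
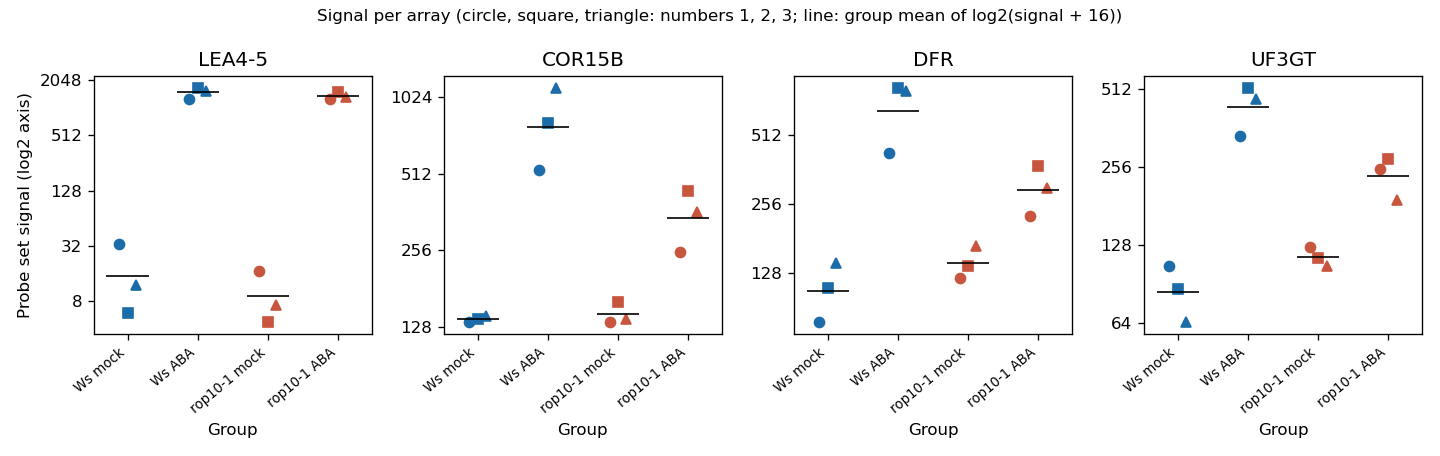
Signal of LEA4-5, COR15B, DFR and UF3GT on each of the 12 arrays (log2 axis), by group, with circles, squares and triangles for replicates numbered 1, 2 and 3 and lines for group means taken on the log2(signal + 16) scale. Under ABA, DFR averaged 680 in Ws and 302 in rop10-1, and LEA4-5 1510 and 1377.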

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

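The tests of the 3 genes below were chosen after their values were seen, except the test of single arrays, and the counts over other splits of the arrays were planned.

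DFR, UF3GT and COR15B rose less under ABA in rop10-1 than in Ws, a difference between genotypes with interactions of -1.45, -1.22 and -1.21 on the log2 scale (SE 0.38, 0.28 and 0.34), a mean of -1.30 (SE 0.297). The 1307 risen probe sets showed no mean loss of this size, as the 95% interval of their difference reached down to only -0.282. That interval bounds the mean of the set and not single members, and the 3 genes were picked by their interactions. Their place below it therefore decides nothing by itself. No single array carried the size, as the mean stayed at -1.15 or below, nearest to 0 without Ws ABA 3. With the replicate block the mean lay -5.43 SE from 0. The 3 genes were picked by their interactions, so that ratio is large by choice and decides nothing about the replicate numbers. Selection stays partly open. Over all 34 list members the largest adjusted limma p of the 3 genes was 0.0464 (0.00714 with the replicate block). This test was put in place of adjustment within each list after the result of the latter was seen. Over all genes each had an adjusted p of 1, and with the block the smallest of any probe set was 0.454. Only 2 of the 12 fits with an array left out kept all 3 under 0.05. Among the 397 probe sets that rose at least 2-fold, 3 had an interaction at or below the mean of -1.30 and 3 had one as large in the other direction. By themselves UF3GT and COR15B did not reach that mean. A weaker induction of these genes in rop10-1 may therefore be a hypothesis for follow-up, not a finding.

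Other splits of the arrays were counted for each comparison. For single comparisons of 3 against 3 arrays the 10 splits, and the 4 that part each same-number pair, are too few for a share under 0.05. There the real split was the 1 with calls in each case, and the highest other split gave 0, against 1042 and 1041 for ABA in Ws and rop10-1 and 5 and 3 for the genotype in mock and ABA (2495, 2486, 7 and 43 with the block). For the average ABA response chance can be excluded, with 1 of 100 splits as high (2475 against 697 in the next) and 1 of 32 with the block (4455 against 0). It can be excluded likewise for the ABA-induced markers, where 1 of 100 permutation splits gave a camera p as small (real p = 2.48e-11, smallest other p = 3.72e-07). For the average genotype difference 3 of 100 splits gave 6 calls or more. The highest gave 666 and put all 4 arrays numbered 1 on a side and all 4 numbered 2 on the other, which points to a structure by replicate number. With the block 1 of the 32 splits that part each pair reached 227, and the next gave 6. Most of these splits also part the mock and ABA arrays of a genotype and number, which correlated at r = 0.345 to 0.711. A difference shared by such arrays is therefore not excluded. For the interaction, with 0 calls observed, all 100 splits reach the count whatever the data, so it decides nothing. Of the 99 other splits 2 gave any call (highest 666).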

How the results depend on the processing

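Leaving out all arrays of a number was chosen after seeing the data, and all other settings were planned. No named gene with a call in the main fit or under a setting changed direction under that setting. Sign changes of genes without a call were not counted. The interaction gave 0 calls under each setting (301 at an unadjusted limma p under 0.05). Pseudocounts, scalings, the trend and shared-probe IDs kept each count within 1.5 times. The replicate block gave 2495 calls for ABA in Ws, 2486 in rop10-1, 4455 for their average, 43 for the genotype under ABA and 227 for its average. A 2-fold minimum left 498, 488 and 566 ABA calls, by its construction. With the 2 groups alone, which use fewer arrays, ABA in Ws gave 571 and the genotype 0 in mock and 0 under ABA. Array weights gave 2481 for ABA in rop10-1, 19 for the genotype under ABA and 15 for its average. The genotype in mock gave 3 with no low filter and 2 with the lowest 50% left out, where its average gave 3, and for weights and filters the cause was not tested. Without all arrays numbered 1, 2 or 3 (8 arrays left), the genotype in mock gave 1, 0 and 0. Without numbers 2 and 3 respectively, ABA in Ws gave 361 and 267, in rop10-1 360 and 295, their average 1130 and 856, the genotype under ABA 14 and 0 and its average 14 and 0.

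With each array left out, calls ranged from 686 (without Ws mock 2) to 1099 for ABA in Ws, 611 (without rop10-1 ABA 3) to 1197 in rop10-1, 1880 to 2704 for the average, 0 to 5 for the genotype in mock, 0 to 4 under ABA (0 without rop10-1 ABA 1 or 3) and 6 to 10 for its average. The difference in response size ranged from -0.114 to 0.0575 for the risen and from -0.0464 to 0.0672 for the fallen set. The adjusted p of the ABA-induced markers ranged from 0.0185 to 0.465 for the interaction, 0.0146 to 0.439 for the genotype under ABA and 0.0403 to 0.411 for its average. The alternative settings for ROP10 expression were not run, since no probe set was assigned to it. Low signal limits fold changes, which the pseudocount of 16 shrinks for genes such as LEA4-5 in mock.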

Other observations

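The tests on chromosome position and gene families were chosen after the data were seen, except the test of the uncalled genes of the window.

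Replicate number moved many genes. Between the numbers, 3192 of 15923 probe sets differed by limma, with 4 arrays each. The 66 plastid-encoded genes averaged 10.6 ± 0.077, 10.9 ± 0.173 and 11.4 ± 0.0854 (log2, SD, n = 4) on arrays numbered 1, 2 and 3, and 51 of them passed. The Rubisco gene rbcL averaged 7.67, 8.09 and 9.49 and the photosystem gene psbA 11.8, 12.2 and 13.1. The defensin genes PDF1.2 and PDF1.4 were highest with number 1 (8.53 and 10.0, against 6.47 and 7.78 with number 2), as was the sugar transporter gene SWEET10 (9.29 against 6.76 and 6.99). The zinc finger gene STZ was highest with number 2 (11.1 against 9.51 and 8.96). The transcription factor gene AT3G10040 of the hypoxia list averaged 7.15, 5.38 and 8.62. The 25S rRNA control signal was 118 to 178 on arrays numbered 3, 60 to 84.1 on those numbered 1 and 42.1 to 122 on those numbered 2.

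Autophagy genes had slightly higher signal in rop10-1. Among 35 gene families formed from symbols, the 8 ATG genes had a median log2 difference of 0.28 in mock (camera adjusted p = 0.000522), 0.21 under ABA (adjusted p = 0.0345, 0.05 with the replicate block) and 0.24 in the average (adjusted p = 0.000318). None held with an estimated correlation (adjusted p = 0.323, 0.862 and 0.456). In mock the block also brought CML and LSM (higher, adjusted p = 0.0267 each) and NET (lower, 0.0431) under 0.05, from 0.0703, 0.06 and 0.0703 without it, and none held with an estimated correlation (0.323, 0.559 and 0.766). ATG8B had 0.45 (SE 0.12) and ATG8H 0.34 (SE 0.11) in the average, and no ATG gene passed by itself except ATG8B with the block (adjusted p = 0.0452). Under ABA the 5 WRKY genes had a median of 0.39 (adjusted p = 0.0345, which rose to 0.0733 with the block and 0.862 with an estimated correlation), with WRKY6 at 0.92 (SE 0.36). With the replicate block the 5 called genes with a name that were higher in rop10-1 by most on average were, chosen after their values were seen, AT2G41730 (2.63), ZCF37 (2.59), AT1G78410 (2.25), AT4G37290 (2.13) and AT2G04050 (2.09), and that list depends on single arrays (7 calls without rop10-1 mock 2).

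The 3 named genes that differed between rop10-1 and Ws without the block lay close together on chromosome 5. Only probe sets with a single gene could be placed. In the average over treatments these were 3 of the 6 called without the block and 106 of the 227 called with it. The other calls were left out of the tests of position. All 3 named genes called without the block, Fes1C, AT5G01350 and AT5G01015, and 6 of the 106 called with it lay in the 100 tested genes from AT5G01010 to AT5G03610, where chance placement gave as many in a share of 3e-04 and 0.403 of 10000 permutations. The first, and a scan of mean ranks that gave a permutation p of 0.046 for this window, were computed only after the 0.403 was seen, so chance stays open for the genes called with the block. The uncalled genes there had a median absolute statistic of 1.51 against 1.03 elsewhere, at the percentile 100 of other windows, which is consistent with a chromosome segment that differs between the lines. Fes1C, AT5G01350 and AT5G01015 were called in the mock comparison, whatever their difference under ABA. Each gene was signed by its mock difference, so that AT5G01015 counted as positive. Their mean difference was then 1.37 in mock and 1.26 under ABA (change -0.115, SE 0.114, 95% interval -0.377 to 0.147). A difference that depends on ABA therefore cannot account for these 3 genes. For the other 3 it stays open, since their median ratio of 0.736 between the smaller and the larger of the mock and ABA differences was taken over genes called for the average of both. Linkage to ROP10 on the reference map cannot account for the chromosome 5 genes, since ROP10 lies on chromosome 3 there. The 100 genes around it held 3 calls, a number reached in 12.3% of windows, which decides nothing about chromosome 5. The chromosome arrangement of the mutant line itself was not tested. A probe mismatch to a variant in rop10-1 would lower its signal, but 5 of the 6 genes were higher there; a mismatch in Ws, or another background of the mutant line, stays open.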
